A study of Mus musculus with 12 samples.

How the data were processed

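RNA was measured on 12 one-colour whole-transcript arrays, 1 per sample, from whole liver and from primary hepatocytes of WT mice (floxed Jnk1, intact Jnk2) and of JNKΔhepa mice, in which Jnk1 is deleted in hepatocytes by a Cre driven by albumin and alpha-fetoprotein regulatory elements and Jnk2 is absent from the whole animal. Per the labels, 6 male mice, 3 of each genotype, gave both a liver and a hepatocyte sample, the WT animals were littermates, and RNA was amplified and biotin-labelled with a whole-transcript expression kit. The groups and the replicate numbers were taken from the sample labels, and every column of the value table was matched to a sample by its label.

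The deposited values are on a log2 scale, which was read from their range and from the submitters' processing notes, which name RMA (robust multi-array average: background correction, quantile normalisation and summary per probe set) without a version. The log base, the software, the probe-set definition and the genome build are not given in the sources used here. The quantiles of the deposited values were close among the 6 liver arrays and among the 6 hepatocyte arrays but differed between the tissues: the array medians were 4.09 to 4.12 in liver and 3.22 to 3.28 in hepatocytes. The tissues therefore appear to have been normalised separately, which the sources used here do not state. A level set across the tissues depends on this. The table holds neither detection calls nor a background estimate, so the size of a change is given as a lower bound where any array of the dimmer group read below the median of all its probe sets. Where arrays of both groups did so, the size is called not exact. This rule was set after the values were seen.

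The table held 35556 probe sets with 0 missing values, and 0 columns were left without a sample. The platform annotation gave exactly 1 gene symbol to 21218 probe sets, several to 1881, and 12457 are not named here. The probe set with the highest mean over all arrays stood for each of 18820 genes, of which 1386 had several. A RefSeq gene table (assembly GRCm38.p6) held the Entrez number of 18790 of these genes and updated 0 symbols. It was used for names and for which genes neighbour each other. No coordinates are given, because the build behind the platform annotation is not stated.

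Group means were fitted to the 12 arrays with limma 3.58.1 (R 4.3.3, statmod 1.5.0), so that all groups shared an estimate of the spread (8 residual and 4.76 prior degrees of freedom). The contrasts were JNKΔhepa minus WT in liver, the same in hepatocytes, the hepatocyte effect minus the liver effect (interaction), and hepatocytes minus liver averaged over the genotypes. Tests were two-sided, without a filter on dim probe sets, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The overlap of the liver and hepatocyte calls was tested with Fisher's exact test. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

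The contrasts, the threshold, the other settings tried, the 33 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 778 entries, of which 685 were measured by a probe set with 1 symbol. They covered the JNK cascade, AP-1 and immediate early genes, bile acid synthesis and transport, PPAR-alpha targets and fatty acid oxidation, fatty acid synthesis, sterol synthesis, xenobiotic metabolism, NRF2 targets and glutathione, the unfolded protein response, heat shock, apoptosis and necroptosis, p53 targets, the cell cycle, cytokines with chemokines and NF-kB targets, the acute phase, the interferon response, glucose metabolism and insulin signalling, and the circadian clock. They also covered male-biased and female-biased liver genes, pericentral and periportal hepatocyte genes, hepatocyte identity, fetal and tumour-associated liver genes, dedifferentiation and cytoskeleton, extracellular matrix, and markers of stellate cells, Kupffer cells and macrophages, sinusoidal endothelium, cholangiocytes, lymphocytes, neutrophils and monocytes, and erythroid cells. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. The p with an estimated correlation is given beside it. The rotation test fry, which asks whether a list's genes move on balance to one side of 0, was a second test.

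Genes were named by rule. In the genotype comparisons these were Mapk8 and Mapk9, the 10 largest increases and decreases past the threshold whose arrays did not overlap between genotypes, and from each list up to 3 members with the smallest p that passed, or the member with the smallest p where none did. In the interaction and between the tissues the 10 largest in each direction past the threshold and the same list members were eligible, topped up to 5 by smallest p where fewer passed. Symbols of predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were left out of the largest changes. The rule named 116 genes between the tissues, and those printed were picked from them after the values were seen, mostly genes whose direction holds under all 3 scalings. A few further genes, such as list members that missed the threshold and genes in position clusters, were also chosen after their values were seen.

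Alternatives included another quantile normalisation of the 12 arrays, centring of each array on its median, a filter at the 30th percentile of mean level, all probe sets, a trended and robust variance, array weights, a 1.5-fold or stricter p threshold, the arrays of a tissue alone, the mouse as a random or fixed block, and leaving out each array in turn. The settings added after the data were seen were the genes within 20 Mb of Mapk9 left out, the list tests under other scalings, without each array, with the mouse as a block and without Mapk8 and Mapk9 in the lists, and 4 further settings for the overlap. Liver and hepatocyte samples of the same number came from the same mouse, by the mouse numbers in the labels. Their deviations from the group means correlated at −0.0133 to 0.0982 (consensus 0.0487). The same number in the other genotype names a different mouse.

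The fit was tested on simulated data made from the real means and spreads, with 50 genes changed at each size among 18820. In liver, 20, 45, 50 and 49 of 50 genes were recovered at log2 sizes of 0.5, 1, 1.5 and 2, with 8 false calls. In hepatocytes, 24, 47, 50 and 50 of 50 were recovered, with 10 false calls. In the liver simulation 1 of 1 changed list was recovered and 0 other lists were called. Genes were simulated independently of each other, whereas the estimated correlation within the real lists reached 0.625. The simulation therefore does not test the preset correlation on the real lists.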

Results

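Gene expression was measured in whole liver and in primary hepatocytes, the parenchymal cells isolated from liver, of WT and JNKΔhepa mice. JNKΔhepa mice lack Jnk1 (Mapk8) in hepatocytes and Jnk2 (Mapk9) in all cells. The 4 groups held 3 arrays each, from 6 mice that gave both tissues, and 18820 genes were tested. Within a group, the arrays correlated at r = 0.9865 to 0.9928 across probe sets.

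Mapk9, which encodes JNK2, was far lower in all JNKΔhepa arrays of both tissues. In liver the WT arrays of replicates 1, 2 and 3 read 8.64, 8.69 and 8.59 on the log2 scale and the JNKΔhepa arrays 2.85, 2.33 and 3.02. In hepatocytes the WT arrays read 8.10, 7.74 and 8.05 and the JNKΔhepa arrays 2.62, 2.57 and 2.29. Mapk9 thus fell at least 59.9-fold in liver (log2 change −5.90, SE 0.159, limma adjusted p = 4.02e-10) and at least 44.4-fold in hepatocytes (log2 change −5.47, SE 0.159, adjusted p = 1.05e-09). Its JNKΔhepa readings lie near the lower quartile of all probe sets (2.61 to 2.66 on the liver arrays and 2.09 to 2.15 on the hepatocyte arrays), so these folds are lower bounds. Folds of other genes are written with "at least" where any array of the dimmer group read below the median of its probe sets. A log2 change with such readings is marked as dim or stands beside such a fold, and its size is a lower bound too. Where arrays of both groups read below the median, the size is called not exact.

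Mapk8, which encodes JNK1, fell much less. Its liver values were 6.40, 6.39 and 6.37 in WT and 5.95, 5.93 and 6.07 in JNKΔhepa replicates 1, 2 and 3. The hepatocyte values were 5.62, 5.51 and 5.66 in WT and 4.952, 4.999 and 5.011 in JNKΔhepa. The log2 change of Mapk8 was −0.40 in liver (1.32-fold, SE 0.0762, limma adjusted p = 0.027) and −0.61 in hepatocytes (1.52-fold, SE 0.0762, adjusted p = 0.00183), and every JNKΔhepa array lay below every WT array of its tissue. The labels do not say which part of Mapk8 is removed, so the probe set can lie partly or wholly outside it and its value does not measure how complete the deletion was. The liver call for Mapk8 was lost without WT replicate 1 (limma adjusted p = 0.109), WT replicate 2 (0.096), WT replicate 3 (0.0532), JNKΔhepa replicate 1 (0.12) or JNKΔhepa replicate 2 (0.106).

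**Figure D1:**
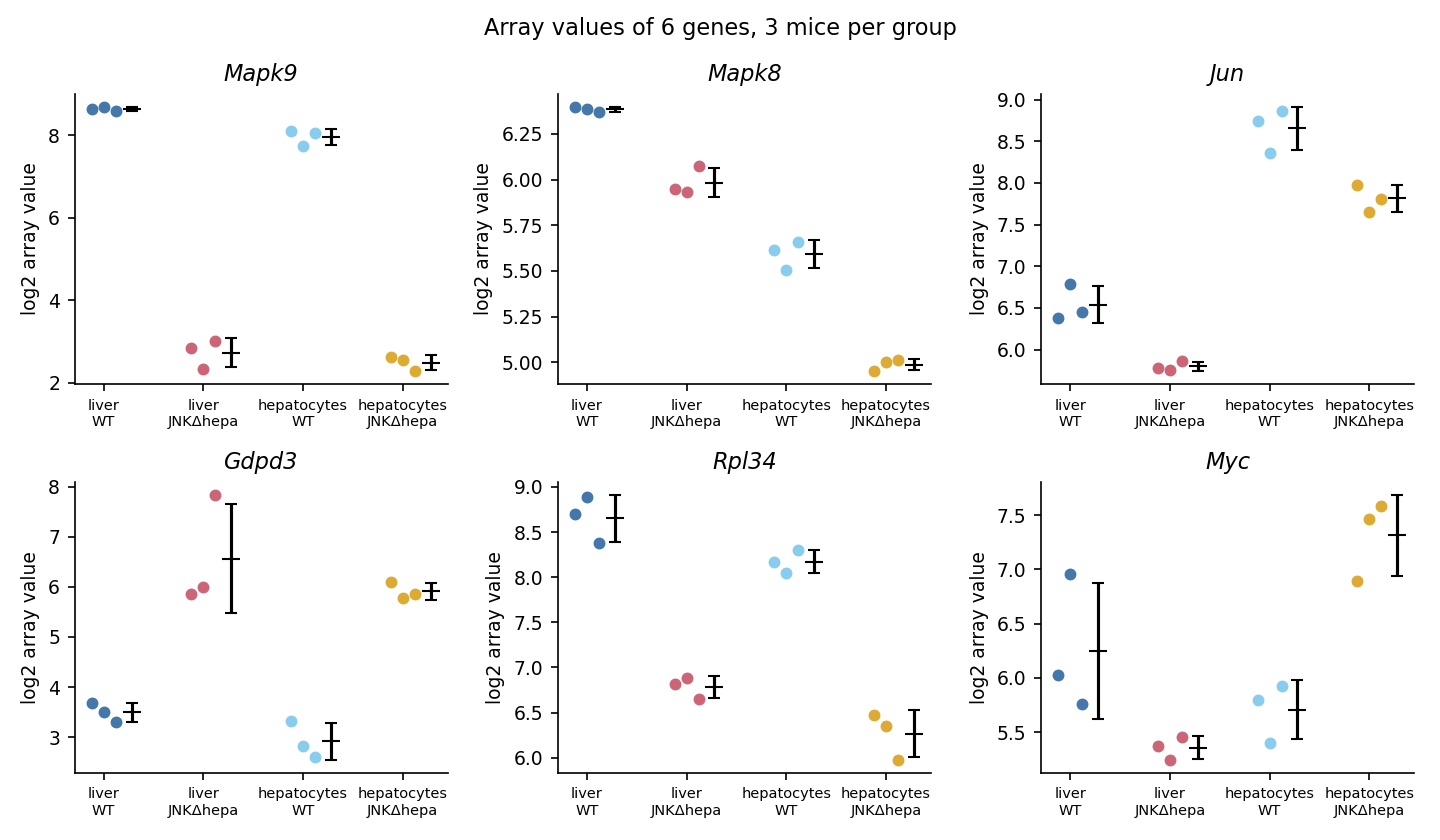
Log2 expression of Mapk9, Mapk8, Jun, Gdpd3, Rpl34 and Myc on each array (points), with the mean and SD of each group (n = 3), for liver and hepatocytes of WT and JNKΔhepa mice. Mapk9 dropped from 8.64 to 2.74 in liver and from 7.96 to 2.49 in hepatocytes, while Myc differed between genotypes past the threshold in hepatocytes (5.71 against 7.31). In liver Myc was lower in JNKΔhepa, without passing the threshold.

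The first comparison asked which transcripts differ between JNKΔhepa and WT in whole liver. Besides Mapk9, the largest decreases were in the alcohol dehydrogenase pseudogene Adh6-ps1 (at least 27.9-fold, log2 change −4.80, SE 0.363, limma adjusted p = 3.75e-05) and in Nnmt, which methylates nicotinamide (11.8-fold, log2 change −3.56, SE 0.556, adjusted p = 0.00945). Pttg1, which encodes securin, fell at least 4.97-fold (adjusted p = 3.75e-05), and Rpl34, a protein of the large ribosomal subunit, fell 3.65-fold (adjusted p = 4.72e-05). The largest increases were in Gdpd3, a glycerophosphodiester phosphodiesterase (at least 8.39-fold, log2 change 3.07, SE 0.388, adjusted p = 0.00269), and in the interferon-induced Ifi44l (at least 5.48-fold, SE 0.124, adjusted p = 5.73e-07). Jun, the AP-1 subunit phosphorylated by JNK, fell 1.67-fold (log2 change −0.74, SE 0.14, adjusted p = 0.0264). The call for Jun, genotype effect in liver, was lost without replicate WT 2 (0.103), JNKΔhepa 1 (0.0944), JNKΔhepa 2 (0.0931) or JNKΔhepa 3 (0.0686), in limma adjusted p.

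In liver 174 genes passed the threshold, 105 higher and 69 lower in JNKΔhepa, and 120 of these changed at least 1.5-fold. At an unadjusted p under 0.05 there were 2360 genes, where chance gives 941. In 3846 genes (20.4%) the arrays of the genotypes did not overlap, against 10% by chance. Other large increases were in Defb1, a beta-defensin (at least 3.67-fold), the zinc transporter gene Slc39a2 (3.31-fold), Apoa4, an apolipoprotein (2.94-fold), Cox6b2, a cytochrome c oxidase subunit isoform (at least 2.82-fold), the sorting receptor gene Sorl1 (at least 2.76-fold), Naip2, an inflammasome receptor (at least 2.66-fold), C1ql4 (2.1-fold, not exact) and Tex12 (at least 1.99-fold). Other large decreases were in C6, a complement component (3.38-fold), the steroid dehydrogenase gene Hsd3b3 (2.75-fold), Plppr5 (at least 2.4-fold), Zfp39 (2.39-fold) and Tifa (2.34-fold). Among these 13 genes the limma adjusted p ran from 0.000597 for Apoa4 to 0.0487 for C6. Some calls were lost without single arrays, listed with the limma adjusted p. For C1ql4, genotype effect in liver, they were WT 2 0.0618, JNKΔhepa 1 0.0675, JNKΔhepa 3 0.0657. For Tex12 they were WT 1 0.11, WT 3 0.0776, JNKΔhepa 1 0.122, JNKΔhepa 2 0.116. For C6 they were WT 1 0.176, WT 2 0.159, JNKΔhepa 1 0.122, JNKΔhepa 2 0.168, JNKΔhepa 3 0.0725. For Tifa it was WT 1 0.0574. A second probe set of Apoa4 read 0.74, less than the 1.56 of the probe set used.

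Of 27 measured PPAR-alpha targets, mostly genes of fatty acid oxidation, 4 rose past the threshold in liver and 12 did adjusted over the list alone. All 27 had values above 0 (median log2 change 0.39; camera adjusted p = 1.72e-12; adjusted p = 0.324 with an estimated correlation). The 4 were Acadm, the medium-chain acyl-CoA dehydrogenase (log2 change 0.46, adjusted p = 0.0125), the peroxisomal enzyme gene Ehhadh (0.71, adjusted p = 0.0274), the lipid droplet gene Plin2 (0.57, adjusted p = 0.0129) and the hormone gene Fgf21 (0.77, dim in WT, adjusted p = 0.0373). Of 29 interferon response genes, Rsad2 (log2 change 0.89, adjusted p = 0.00701) and Xaf1 (0.56, adjusted p = 0.0101) rose and Oasl1 fell (−0.60, adjusted p = 0.0477). Adjusted over the list alone, 12 interferon genes rose and 1 fell (camera adjusted p = 1.57e-07; adjusted p = 0.324 with an estimated correlation). Of 27 bile acid genes, Cyp8b1, the sterol 12-alpha-hydroxylase (log2 change 0.63, adjusted p = 0.0403), and the transporter gene Slco1a4 (0.78, adjusted p = 0.0339) rose. Adjusted over the list alone, 5 bile acid genes rose and 1 fell (camera adjusted p = 0.00526; adjusted p = 0.13 with an estimated correlation). The liver call for Fgf21 was not tested without single arrays. Arrays without which another gene call was lost are listed with the limma adjusted p, and those of Oasl1 and Cyp8b1 are all 6. For Acadm, genotype effect in liver, they were WT 1 0.0675, JNKΔhepa 2 0.0609, JNKΔhepa 3 0.0651. For Ehhadh they were WT 1 0.132, WT 2 0.104, JNKΔhepa 1 0.074, JNKΔhepa 2 0.051, JNKΔhepa 3 0.114. For Plin2 they were WT 1 0.0717, JNKΔhepa 1 0.0681, JNKΔhepa 3 0.0667. For Xaf1 it was JNKΔhepa 1 0.053. For Slco1a4 they were WT 1 0.136, WT 2 0.129, JNKΔhepa 2 0.114, JNKΔhepa 3 0.103. For Oasl1, genotype effect in liver, they were WT 1 0.18, WT 2 0.096, WT 3 0.0721, JNKΔhepa 1 0.0681, JNKΔhepa 2 0.101, JNKΔhepa 3 0.157. For Cyp8b1 they were WT 1 0.0535, WT 2 0.117, WT 3 0.0992, JNKΔhepa 1 0.0547, JNKΔhepa 2 0.0698, JNKΔhepa 3 0.116.

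Male-biased liver genes, sterol synthesis and heat shock genes tested lower in JNKΔhepa liver at the preset correlation but not with an estimated one. Of 17 male-biased genes, C6 fell past the threshold (a call lost without the arrays named above), and 10 fell and 1 rose adjusted over the list alone (median log2 change −0.49, camera adjusted p = 3.94e-09; adjusted p = 0.324 with an estimated correlation). In sterol synthesis 0 of 20 genes passed limma over all genes and 9 fell adjusted over the list alone (median −0.42, camera adjusted p = 8.14e-08; adjusted p = 0.423 with an estimated correlation). Msmo1, a sterol demethylation enzyme, had a log2 change of −0.74 (SE 0.184, adjusted p = 0.0906). All 12 heat shock genes had values below 0. On the probe sets used, 0 passed over all genes and 6 fell adjusted over the list alone (median −0.31, camera adjusted p = 2.55e-07, adjusted p = 0.0808 with an estimated correlation). Other probe sets of Hspa8, not part of these counts, read −0.35 (SE 0.0893) and −1.91 (SE 0.125), against −0.38 in the one used. Hsph1, a chaperone of the HSP110 family, had a log2 change of −0.77 (SE 0.182, adjusted p = 0.0734).

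The JNK cascade list tested lower in liver only through the targeted genes it holds: without Mapk8 and Mapk9 the other 21 genes had a mean log2 change of 0.0239 and did not pass (camera adjusted p = 0.679, fry 0.881). With them, Mapk9, Mapk8 and Dusp8, a phosphatase of JNK (log2 change −0.59, not exact, adjusted p = 0.0101), fell out of 23 genes; adjusted over the list alone 3 fell and 2 rose (camera adjusted p = 0.0344; adjusted p = 0.324 with an estimated correlation). Of 27 AP-1 and immediate early genes, Jun and the antiproliferative gene Btg2 (−0.68, adjusted p = 0.0473) fell, and 5 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.546 with an estimated correlation). In the other lists that tested lower, 0 genes passed limma over all genes. They were the cell cycle (median −0.19, camera adjusted p = 0.0103; adjusted p = 0.896 with an estimated correlation; 0 adjusted over the list alone) and the unfolded protein response (median −0.0993, camera adjusted p = 0.0103; adjusted p = 0.482 with an estimated correlation; 2 fell adjusted over the list alone). The circadian clock (median −0.20, camera adjusted p = 0.0103; adjusted p = 0.324 with an estimated correlation; 1 fell adjusted over the list alone) and stellate cell markers (median −0.101, camera adjusted p = 0.0198; adjusted p = 0.482 with an estimated correlation; 2 fell adjusted over the list alone) were the others. Single arrays without which the gene call was lost follow with the limma adjusted p. For Btg2 they were WT 1 0.155, WT 2 0.151, JNKΔhepa 1 0.178, JNKΔhepa 3 0.15. List calls were lost too, by replicate: JNK cascade without WT 1 (0.0517), WT 2 (0.0502) or JNKΔhepa 1 (0.0875); AP-1 genes without WT 1 (0.0517) or JNKΔhepa 3 (0.0776); cell cycle without JNKΔhepa 2 (0.0924). The same held for the unfolded protein response without WT 2 (0.0906), the clock without WT 3 (0.0744), the stellate markers without WT 1 (0.0755) or JNKΔhepa 3 (0.113).

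The other 21 lists did not pass in liver. Among them Elovl5 (log2 change 0.52, limma adjusted p = 0.0104) rose in fatty acid synthesis (camera adjusted p = 0.363), Polk (0.63, adjusted p = 0.0267) in p53 targets (0.855), Hao2 (0.53, adjusted p = 0.0478) in female-biased genes (0.934) and the matrix protein gene Sparc (0.67, adjusted p = 0.0141) in extracellular matrix (0.304). The keratin gene Krt23 (0.75, adjusted p = 0.0102) and the mucin gene Muc1 (0.64, adjusted p = 0.0195) rose among cholangiocyte markers (camera adjusted p = 0.68). These calls were lost without the arrays listed with the limma adjusted p, all 6 for Polk. For Elovl5, genotype effect in liver, they were WT 1 0.0563, JNKΔhepa 2 0.0521. For Hao2 they were WT 1 0.135, WT 2 0.16, JNKΔhepa 2 0.164, JNKΔhepa 3 0.161. For Sparc they were WT 1 0.0601, WT 2 0.054, JNKΔhepa 1 0.074, JNKΔhepa 3 0.0525. For Polk, genotype effect in liver, they were WT 1 0.118, WT 2 0.0522, WT 3 0.0645, JNKΔhepa 1 0.0944, JNKΔhepa 2 0.101, JNKΔhepa 3 0.0651. For Krt23, genotype effect in liver, they were WT 1 0.0585, JNKΔhepa 1 0.0562. For Muc1 they were WT 1 0.0837, WT 2 0.0648, JNKΔhepa 1 0.0705, JNKΔhepa 2 0.08. The readings of Hao2, Krt23 and Muc1 are dim in both genotypes, so the sizes of their changes are not exact. The camera adjusted p was 0.0689 for dedifferentiation and cytoskeleton, 0.138 for xenobiotic metabolism, 0.138 for Kupffer cell and macrophage markers, 0.403 for the acute phase, 0.422 for endothelial markers and 0.457 for lymphocyte markers. It was 0.679 for NRF2 targets, 0.68 for cytokines, 0.683 for fetal genes, 0.744 for glucose metabolism, 0.744 for pericentral genes and 0.744 for hepatocyte identity. It was 0.855 for erythroid markers, 0.934 for apoptosis, 0.934 for periportal genes and 0.934 for neutrophil and monocyte markers. The median and the test had different signs for hepatocyte identity, female-biased genes and erythroid markers, and the mean and the test for female-biased genes, pericentral genes, neutrophil and monocyte markers and erythroid markers. Adjusted over the list alone, 3 genes passed in fatty acid synthesis, 2 in p53 targets, 3 in glucose metabolism, 2 in cholangiocyte markers, 1 each in xenobiotic metabolism, female-biased genes, dedifferentiation, extracellular matrix and Kupffer cell markers, and 0 in the remaining 12.

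The count of genes past the threshold for the genotype effect in liver was 81 without WT replicate 1, 103 without WT replicate 2, 80 without JNKΔhepa replicate 1, 108 without JNKΔhepa replicate 2, 90 without JNKΔhepa replicate 3 and 408 with array weights. Of 38 named liver calls 18 held without any single array, and the calls lost numbered 17, 13 and 5 without WT replicates 1, 2 and 3 (adjusted p up to 0.18, 0.16 and 0.0992) and 15, 13 and 13 without JNKΔhepa replicates 1, 2 and 3 (up to 0.178, 0.168 and 0.161); for the lists these were 3, 2 and 1 of 12 (up to 0.0755, 0.0906 and 0.0744) and 1, 1 and 2 (up to 0.0875, 0.0924 and 0.113).

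**Figure D2:**
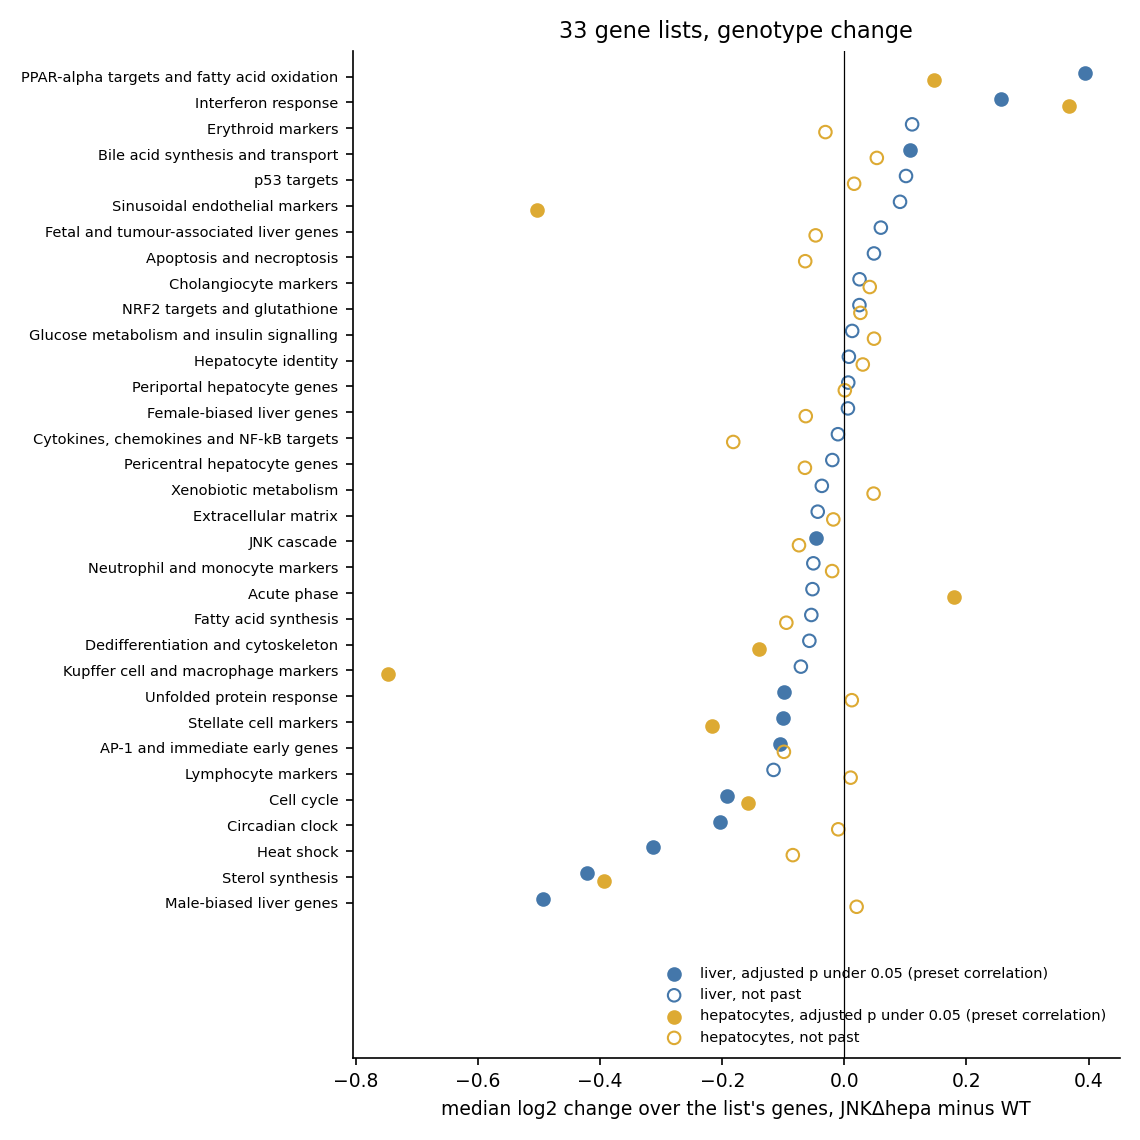
Median log2 change (JNKΔhepa minus WT) over the measured members of each of the 33 gene lists, in liver and in hepatocytes; filled points have a camera adjusted p under 0.05 at the preset correlation. PPAR-alpha targets had a median of 0.39 in liver, and Kupffer cell markers a median of −0.748 in hepatocytes.

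The second comparison asked the same of primary hepatocytes. Adh6-ps1 (at least 22.2-fold, log2 change −4.47, limma adjusted p = 6.99e-05), Nnmt (7.3-fold, log2 change −2.87, adjusted p = 0.029) and Rpl34 (3.74-fold, log2 change −1.90, adjusted p = 6.99e-05) fell in JNKΔhepa hepatocytes, as did Cyp17a1, a steroid hydroxylase (3.81-fold, SE 0.402, adjusted p = 0.0444). Gdpd3 rose at least 7.98-fold (log2 change 3.00, SE 0.388, adjusted p = 0.00238), Socs2, a suppressor of growth hormone signalling, 4.64-fold (SE 0.4, adjusted p = 0.022) and Cox6b2 at least 3.78-fold (SE 0.174, adjusted p = 0.000181). The transcription factor gene Myc rose 3.04-fold (log2 change 1.60, SE 0.262, adjusted p = 0.0125), while Jun fell 1.79-fold (log2 change −0.84, SE 0.14, adjusted p = 0.0135). Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, fell 2.01-fold (log2 change −1.01, SE 0.157, adjusted p = 0.00919). Myc went the other way in liver, without passing there. Its liver arrays read 6.03, 6.96 and 5.76 in WT and 5.37, 5.25 and 5.45 in JNKΔhepa. The call for Nnmt, genotype effect in hepatocytes, was lost without replicate WT 1 (limma adjusted p = 0.108), WT 2 (0.0572), WT 3 (0.0581), JNKΔhepa 2 (0.132) or JNKΔhepa 3 (0.116), and that for Cyp17a1, genotype effect in hepatocytes, without WT 1 (0.122), WT 2 (0.0809), WT 3 (0.0824), JNKΔhepa 2 (0.152) or JNKΔhepa 3 (0.169). The same held for Socs2 without WT 1 (0.0707), WT 3 (0.0902), JNKΔhepa 2 (0.0683) or JNKΔhepa 3 (0.0687), for Myc, genotype effect in hepatocytes, without JNKΔhepa 2 (0.0656) or 3 (0.068), for Jun, genotype effect in hepatocytes, without WT 1 (0.0704), WT 3 (0.0614), JNKΔhepa 2 (0.0706) or 3 (0.061), and for Ppargc1a without WT 3 (0.0518) or JNKΔhepa 2 (0.0564).

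In hepatocytes 158 genes passed, 69 higher and 89 lower in JNKΔhepa, and 119 of these changed at least 1.5-fold. There were 2363 genes at an unadjusted p under 0.05, where chance gives 941. In 2762 genes (14.7%) the arrays of the genotypes did not overlap, against 10% by chance. Other large decreases were in Pttg1 (3.25-fold), Tifa (at least 3.23-fold), Cd74, the invariant chain of MHC class II (3.11-fold), Hhex, a homeobox transcription factor (3.05-fold), and the glycosyltransferase gene Galnt7 (at least 2.84-fold). Other large increases were in Naip2 (at least 2.68-fold), Apoa4 (2.57-fold), the steroid dehydrogenase gene Hsd3b2 (2.56-fold), the interferon-induced Ifit1 (2.55-fold), Sorl1 (at least 2.42-fold) and Kdm2b, a histone demethylase (2.33-fold). Among these 11 genes the limma adjusted p ran from 6.99e-05 for Kdm2b to 0.0323 for Ifit1. Single arrays without which a call was lost are listed with the limma adjusted p. For Cd74, genotype effect in hepatocytes, they were WT 1 0.0566, WT 3 0.0516, JNKΔhepa 2 0.0599, JNKΔhepa 3 0.0606. For Ifit1, genotype effect in hepatocytes, they were WT 1 0.0996, WT 2 0.0595, WT 3 0.0581, JNKΔhepa 2 0.14, JNKΔhepa 3 0.14. A second probe set read 0.98 for Apoa4 (1.36 in the one used), and 1.86 (SE 0.21) for Socs2 (2.22 in the one used). In liver the second Socs2 probe set read −0.45 and the one used −0.44. The one used did not pass in liver or in the interaction.

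Markers of sinusoidal endothelium and macrophages tested lower in JNKΔhepa hepatocyte preparations at the preset correlation but not with an estimated one. All 21 endothelial markers had values below 0; 0 passed limma over all genes and 19 fell adjusted over the list alone (median log2 change −0.503, camera adjusted p = 8.82e-16; adjusted p = 0.243 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, had a log2 change of −0.60 (SE 0.132, adjusted p = 0.0568). Of 19 Kupffer cell and macrophage markers, the complement gene C1qb (log2 change −1.08, adjusted p = 0.0225) and the ficolin gene Fcna (−0.79, adjusted p = 0.0272) fell, and 15 fell and 1 rose adjusted over the list alone (median −0.748, camera adjusted p = 6.31e-10; adjusted p = 0.349 with an estimated correlation). Of 18 stellate cell markers Ecm1 fell (−0.71, adjusted p = 0.01), and 6 fell adjusted over the list alone (median −0.216, camera adjusted p = 1.77e-06; adjusted p = 0.243 with an estimated correlation). The marker calls were lost without single arrays, listed with the limma adjusted p. For C1qb, genotype effect in hepatocytes, they were WT 1 0.108, WT 3 0.0856, JNKΔhepa 2 0.0599, JNKΔhepa 3 0.0748. For Fcna they were WT 1 0.129, WT 3 0.115, JNKΔhepa 2 0.123, JNKΔhepa 3 0.13. For Ecm1 they were WT 3 0.0516, JNKΔhepa 2 0.0564, JNKΔhepa 3 0.0606. The mean change was −0.48 for endothelial, −0.553 for Kupffer cell and −0.302 for stellate markers, and 0.0305 for 24 hepatocyte identity genes (95% interval −0.0356 to 0.0965).

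Moving with these markers, dedifferentiation and cytoskeleton genes tested lower: Anxa5, an annexin (log2 change −0.93, limma adjusted p = 0.00399), and the galectin gene Lgals1 (−0.66, adjusted p = 0.0258) fell out of 26, and 6 fell adjusted over the list alone (median −0.139, camera adjusted p = 6.2e-06; adjusted p = 0.243 with an estimated correlation). The call for Lgals1 was lost without single arrays, listed with the limma adjusted p. For Lgals1 they were WT 1 0.118, JNKΔhepa 1 0.055, JNKΔhepa 2 0.087, JNKΔhepa 3 0.089. All 20 sterol synthesis genes had values below 0; 0 passed over all genes and 1 fell adjusted over the list alone (median −0.393, camera adjusted p = 1.09e-07; adjusted p = 0.433 with an estimated correlation). Nsdhl, a sterol dehydrogenase, had a log2 change of −0.39 (adjusted p = 0.0917). Cell cycle genes had a median of −0.158, with 0 of 26 past over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00383; adjusted p = 0.699 with an estimated correlation).

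Of 29 interferon response genes, 4 rose past the threshold in hepatocytes and 7 had values below 0. Ifit1 (log2 change 1.35, limma adjusted p = 0.0323), Rsad2 (1.12, adjusted p = 0.0014), the RNA sensor gene Dhx58 (0.86, adjusted p = 0.0333) and Xaf1 (0.53, adjusted p = 0.0141) were the 4, and 13 rose and 1 fell adjusted over the list alone (median 0.368, camera adjusted p = 3.28e-07; adjusted p = 0.349 with an estimated correlation). Acute phase genes had values above 0 in 23 of 26, with 0 past over all genes and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.000406; adjusted p = 0.699 with an estimated correlation). Fgf21 rose among 27 PPAR-alpha targets (0.85, adjusted p = 0.0233), and 2 rose adjusted over the list alone (median 0.147, camera adjusted p = 0.000406; adjusted p = 0.699 with an estimated correlation). The call for Dhx58 was not tested without single arrays. Other gene calls here were lost without these arrays, with the limma adjusted p. For Ifit1, genotype effect in hepatocytes, they were WT 1 0.0996, WT 2 0.0595, WT 3 0.0581, JNKΔhepa 2 0.14, JNKΔhepa 3 0.14. For Xaf1, genotype effect in hepatocytes, they were WT 3 0.0581, JNKΔhepa 2 0.0703, JNKΔhepa 3 0.0606. For Fgf21, genotype effect in hepatocytes, they were WT 1 0.06, WT 3 0.0866, JNKΔhepa 2 0.112, JNKΔhepa 3 0.068.

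The other 24 lists did not pass in hepatocytes. In the JNK cascade (camera adjusted p = 0.0515, and 0.668 without the targeted Mapk8 and Mapk9) Mapk9, Mapk8 and Dusp8 (log2 change −0.76, dim in JNKΔhepa, limma adjusted p = 0.0015) fell, and 5 fell and 2 rose adjusted over the list alone. Among AP-1 genes (camera adjusted p = 0.0876) Myc rose while Jun and the matricellular gene Ccn1 (−0.98, adjusted p = 0.0233) fell, and 7 fell and 3 rose adjusted over the list alone. Also falling were the sulfotransferase gene Sult1a1 in xenobiotic metabolism (−1.09, adjusted p = 0.00434; list 0.808), the glutathione transferase gene Gstm2 among NRF2 targets (−0.63, adjusted p = 0.01; list 0.998), Ppargc1a in glucose metabolism (list 0.513), Cyp17a1 among female-biased genes (list 0.183) and the proteoglycan gene Bgn in extracellular matrix (−0.80, adjusted p = 0.0198; list 0.317). Besides those given above, calls were lost without these arrays, with the limma adjusted p. For Ccn1 they were WT 1 0.108, WT 3 0.0918, JNKΔhepa 2 0.087. For Gstm2 it was JNKΔhepa 3 0.0606. For Bgn, genotype effect in hepatocytes, they were WT 1 0.0789, WT 3 0.0848, JNKΔhepa 2 0.0976, JNKΔhepa 3 0.0879. The camera adjusted p was 0.0516 for bile acid genes, 0.0516 for cytokines, 0.144 for heat shock, 0.151 for pericentral genes, 0.27 for apoptosis, 0.474 for hepatocyte identity, 0.474 for fetal genes, 0.54 for male-biased genes, 0.562 for fatty acid synthesis and 0.594 for periportal genes. It was 0.631 for the unfolded protein response, 0.808 for lymphocyte markers, 0.828 for p53 targets, and 0.933 for each of the circadian clock, cholangiocyte, neutrophil and monocyte, and erythroid lists. The median and the test had different signs for the clock, cholangiocyte markers, NRF2 targets, p53 targets and periportal genes, and the mean and the test for the clock, xenobiotic metabolism and erythroid markers. Adjusted over the list alone, 2 genes passed in NRF2 targets, glucose metabolism and extracellular matrix, 1 in xenobiotic metabolism, apoptosis, male-biased, female-biased and pericentral genes, and 0 in the remaining 14.

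The count for the genotype effect in hepatocytes was 73 without WT replicate 1, 387 without WT replicate 2, 80 without WT replicate 3, 315 without JNKΔhepa replicate 1, 63 without JNKΔhepa replicate 2, 61 without JNKΔhepa replicate 3 and 77 from the 6 hepatocyte arrays alone. Of 36 named hepatocyte calls 19 held without any single array, and the calls lost numbered 12, 3 and 14 without WT replicates 1, 2 and 3 (adjusted p up to 0.129, 0.0809 and 0.115) and 1, 16 and 15 without JNKΔhepa replicates 1, 2 and 3 (up to 0.055, 0.152 and 0.169); of 9 lists the cell cycle alone was lost, without WT replicate 2 (0.746, direction turned) and without JNKΔhepa replicate 1 (0.19).

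**Figure D3:**
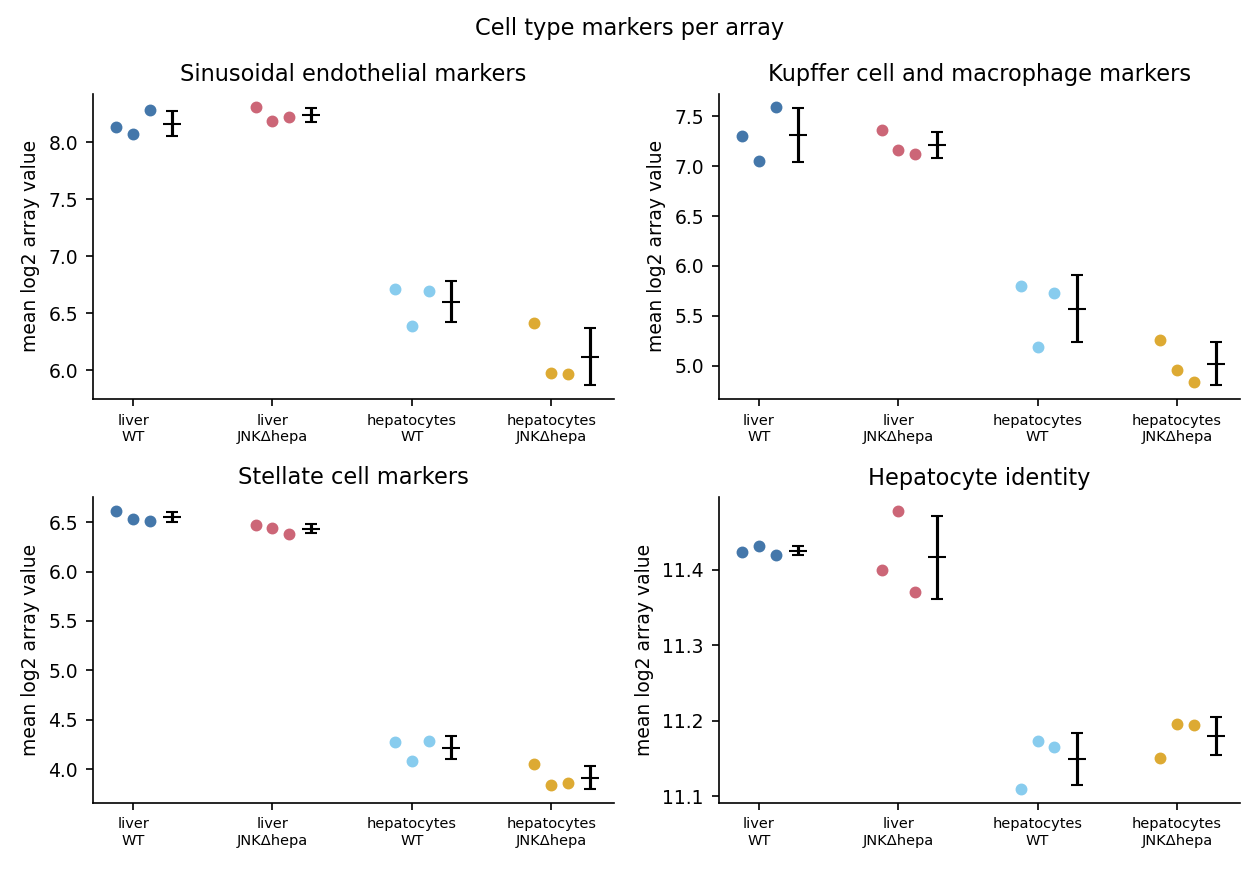
Mean log2 level of the sinusoidal endothelial, Kupffer cell, stellate and hepatocyte identity lists on each array (points), with group means and SD (n = 3), in liver and hepatocytes of both genotypes. The hepatocyte identity mean lay between 11.1 and 11.5 on all arrays, and the tissues appear separately normalised, so levels across them are not directly comparable.

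The calls of the tissues overlapped. Mapk9, Mapk8, Jun, Adh6-ps1, Nnmt, Rpl34, Pttg1, Tifa and Dusp8 fell in both liver and hepatocytes, and Gdpd3, Cox6b2, Apoa4, Sorl1, Naip2, Fgf21, Rsad2 and Xaf1 rose in both. In all, 55 genes passed in both tissues, 22 rising in both, 32 falling in both and 1, Plet1, in opposite directions. Independent lists of these sizes would share 0.711 genes with the same sign. Fisher's exact test of the overlap whatever the sign gave p = 7.59e-74 (two-sided). The tissues came from the same mice, however, so the lists are not independent. Of 174 liver calls 159 had the same sign in hepatocytes, and of 158 hepatocyte calls 140 had the same sign in liver. Across genes, which are not independent replicates, the log2 changes of the tissues correlated at r = 0.402 (rho = 0.272).

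Genes within 20 Mb of Mapk9 on chromosome 11 were called more often: 16 of 392 (4.08%) passed in liver or hepatocytes, against 259 of 18397 elsewhere (1.41%; odds ratio 2.98, 95% interval 1.66 to 5, Fisher's exact p = 0.00023). Pttg1, Zfp39, Atox1, a copper chaperone gene (log2 change −0.84 in liver), and the autophagy kinase gene Ulk2 (−0.79) were among those in this region that fell in both tissues.

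**Figure D4:**
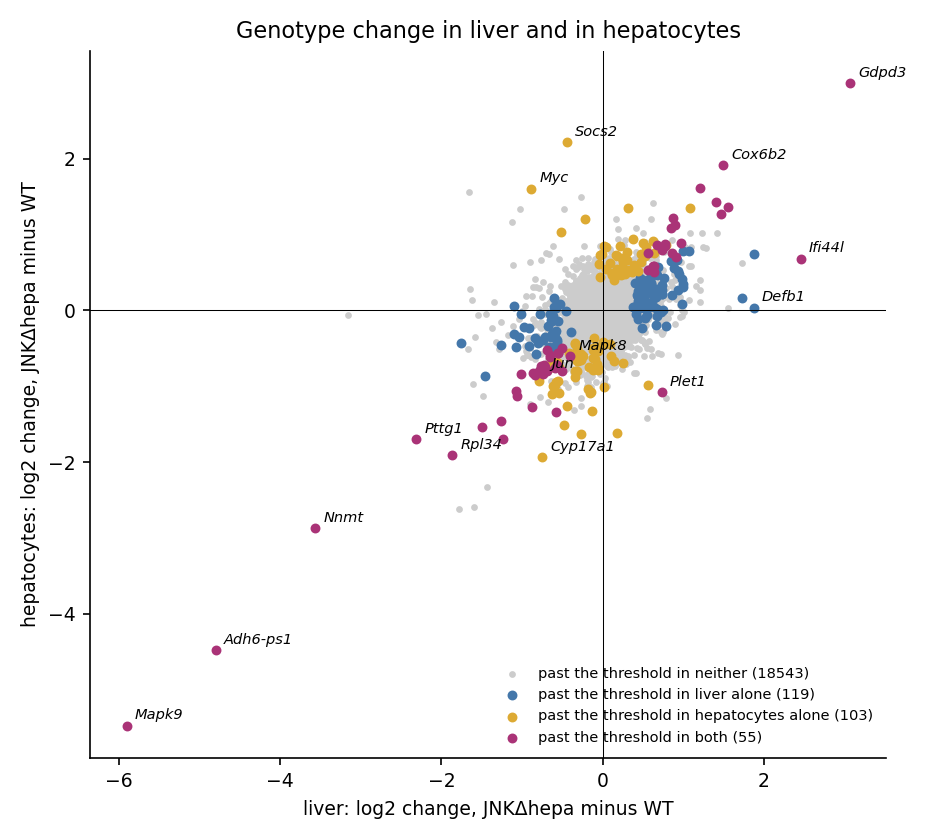
Log2 change (JNKΔhepa minus WT) of each of 18820 genes in liver against that in hepatocytes, coloured by whether the gene passed in liver alone (119), in hepatocytes alone (103), in both (55) or in neither. Of the 55 genes past in both tissues, 54 have the same sign and Plet1 lies in the opposite quadrant.

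The third comparison asked whether the genotype effect differed between liver and hepatocytes. Plet1, which encodes a cell-surface protein of epithelial progenitors, rose in JNKΔhepa liver (6.01 ± 0.0981 in WT and 6.74 ± 0.193 in JNKΔhepa, SD, n = 3) and fell in hepatocytes (3.12 ± 0.293 and 2.04 ± 0.225), an interaction of −1.82 (SE 0.217, limma adjusted p = 0.0147). Plet1 was far lower in hepatocytes than in liver, as were the endothelial and macrophage markers that tested lower in JNKΔhepa hepatocytes. Whether its hepatocyte reading comes from cells other than hepatocytes was not tested. Ifi44l rose more in liver (by 2.46 on the log2 scale, SE 0.124) than in hepatocytes (by 0.68, SE 0.124), an interaction of −1.77 (SE 0.176, adjusted p = 0.00365). The hepatocyte readings of both genes are dim in both genotypes, as are the WT liver readings of Ifi44l, so the sizes of these interactions are not exact. These were the 2 genes that passed, while 1359 had an unadjusted p under 0.05 (941 by chance). Myc, with an interaction of 2.495 (SE 0.371, adjusted p = 0.073), B3galt1 with 1.42 (0.0729), Defb1 with −1.84 (0.129, dim on 1 WT liver array), Ccn1 with −1.55 (0.129) and Alas1, the first enzyme of haem synthesis, with 1.55 (0.182) did not pass. Myc read lower in JNKΔhepa liver and higher in JNKΔhepa hepatocytes than in WT. Plet1 was lost without liver WT replicate 1 (0.0564), liver JNKΔhepa replicate 1 (0.0743) or 2 (0.0805), or hepatocyte JNKΔhepa replicate 2 (0.0833) or 3 (0.0781), and for Myc, genotype by tissue interaction reached an adjusted p of 0.0234 without liver WT replicate 2 and 0.0181 without replicate 3. The count was 4 without liver WT replicate 2, 7 without liver WT replicate 3, 4 without liver JNKΔhepa replicate 3, 4 without hepatocyte WT replicate 2, and 1 without liver JNKΔhepa replicate 1 or 2 or hepatocyte JNKΔhepa replicate 2 or 3.

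Among the 9 lists that passed at the preset correlation, the largest median differences were in endothelial, Kupffer cell and male-biased genes; female-biased genes had a median of −0.555 and did not pass (camera adjusted p = 0.301). All 17 male-biased genes had a higher genotype effect in hepatocytes than in liver (median difference 0.469, camera adjusted p = 1.58e-09; adjusted p = 0.456 with an estimated correlation), with 1 gene past adjusted over the list alone. All 21 endothelial markers had a lower one (median −0.564, camera adjusted p = 5.65e-15; adjusted p = 0.456 with an estimated correlation), with 16 past adjusted over the list alone. Of 19 Kupffer cell markers 17 had a lower one (median −0.532, camera adjusted p = 6.5e-05; adjusted p = 0.722 with an estimated correlation), with 2 past adjusted over the list alone.

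The last comparison set hepatocytes against whole liver in both genotypes. The tissues appear separately normalised, which the sources do not state, and the median gene read −0.5847 lower in hepatocytes as deposited. Values in this comparison therefore come from the 12 arrays after quantile normalisation, unless another scale is named. Sizes, and bounds written with "at least", hold on the quantile-normalised scale alone. Stellate cell, endothelial and macrophage genes were far lower in hepatocytes: Pdgfrb, a receptor of pericytes and stellate cells, by at least 6.78-fold (log2 difference −2.76), Cygb by at least 5.05-fold, the scavenger receptor genes Stab1 by 2.51-fold and Stab2 by 2.45-fold, and C1qb by 3.4-fold. The pericentral hepatocyte genes Glul, glutamine synthetase (3.09-fold), and Slc1a2, a glutamate transporter (7.32-fold), were lower as well; as deposited the probe sets of Glul read −1.99 (the one used) and −2.48. Higher in hepatocytes were the immediate early genes Egr1 (10.9-fold, log2 difference 3.45, limma adjusted p = 1.12e-06), Fos (at least 9.35-fold, adjusted p = 1.84e-06) and Jun (6.6-fold, log2 difference 2.72, adjusted p = 4.22e-09), the glycogen-targeting subunit gene Ppp1r3g (at least 11.3-fold, adjusted p = 1.6e-06) and Igfbp1 (6.77-fold). These directions held as deposited, after quantile normalisation and after centring, but the sizes did not. As deposited, the increases named here were smaller and the decreases larger.

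As deposited, 17371 of 18820 genes passed, 146 higher and 17225 lower in hepatocytes. After quantile normalisation 8481 passed, 4341 higher and 4140 lower, and after median centring 13565 passed, 11216 higher and 2349 lower. Under all 3 scalings 2468 genes passed in one direction, 146 higher and 2322 lower. The deposited scale limits the higher side to its own 146 genes, so the balance of this set carries no direction. Without overlap between the tissues as deposited were 13886 genes (73.8%). Dpt, a matrix protein gene (at least 12-fold, adjusted p = 1.61e-09), Plet1 (at least 8.58-fold), Vim (log2 difference −1.97), Cd79b of B cells (−1.40), the cholangiocyte gene Epcam (−1.12) and the chemokine receptor gene Ccr2 (−1.42) were lower in hepatocytes. The hepatocyte readings of the last 3 are dim, and liver readings of Epcam and Ccr2 are dim too, so those 2 differences are not exact. Gadd45g (6.73-fold), Rgs16 (log2 difference 2.53, adjusted p = 0.00303) and the cell cycle inhibitor gene Cdkn1a (2.33, adjusted p = 0.00159) were higher.

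All 18 stellate cell markers passed as lower after quantile normalisation (median −1.62, camera adjusted p = 4.06e-17; adjusted p = 0.031 with an estimated correlation), as did all 21 endothelial markers (median −1.25, camera adjusted p = 6.55e-16; adjusted p = 0.173 with an estimated correlation) and 18 of 19 Kupffer cell markers (median −1.45, camera adjusted p = 2.48e-11; adjusted p = 0.25 with an estimated correlation). The same numbers of these markers passed adjusted over the list alone. Of 17 pericentral genes 13 were lower, 14 past adjusted over the list alone (median −0.504, camera adjusted p = 1.25e-07; adjusted p = 0.0732 with an estimated correlation). Of 27 AP-1 and immediate early genes 16 were higher and 6 lower, 23 past adjusted over the list alone (median 0.526, camera adjusted p = 0.00043; adjusted p = 0.25 with an estimated correlation). As deposited 11 were higher and 14 lower (median −0.238), and the median was 0.617 after centring, so the balance of this list depends on the scaling. The 24 hepatocyte identity genes had a median of −0.0169 (camera adjusted p = 0.951), with 5 higher and 2 lower, 7 past adjusted over the list alone. As deposited 0 were higher and 18 lower (median −0.255), and after centring the median was 0.599, so no direction is given for them.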

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

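The tests of the overlap splits, of how closely the shared calls lie on chromosomes, of paralogous probes and of the marker genes below were chosen only after the results were seen, as were the paired list fits, while the other splits, the Mapk9 region, the liver cell types and the clock tests were written beforehand.

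A test of the difference between tissues singled out Ifi44l (hepatocyte effect minus liver effect −1.772 on the log2 scale) and Plet1 (−1.816). It also singled out the gene lists with these median differences: sinusoidal endothelial markers −0.564, Kupffer cell and macrophage markers −0.532, dedifferentiation and cytoskeleton genes −0.164, PPAR-alpha targets −0.153, circadian clock genes 0.14, unfolded protein response 0.147, acute phase 0.165, heat shock 0.177 and male-biased genes 0.469. With an estimated correlation 0 of these lists passed camera (lowest adjusted p = 0.456), and fry called 0. The preset camera adjusted p was 0.00011 for the acute phase, 0.00292 for PPAR-alpha targets, 0.00302 for heat shock, 0.00617 for the unfolded protein response and 0.0225 for the clock and for dedifferentiation genes. With the mouse as a block, which pairs liver with hepatocytes, 2 genes passed and all 9 lists stayed past the threshold in the same direction. Calls on lists were lost without single arrays for PPAR-alpha targets (liver WT replicate 1, adjusted p = 0.0819; liver JNKΔhepa replicate 3, 0.206; hepatocyte WT replicate 2, 0.0519; hepatocyte JNKΔhepa replicate 1, 0.161) and the unfolded protein response (hepatocyte JNKΔhepa replicate 1, 0.405). The clock call was lost without liver WT replicate 3 (0.173), liver JNKΔhepa replicate 3 (0.0665), hepatocyte WT replicate 1 (0.163) or 3 (0.0612), or hepatocyte JNKΔhepa replicate 3 (0.066). The dedifferentiation call was lost without liver JNKΔhepa replicate 1 (0.194) or 2 (0.0561), hepatocyte WT replicate 1 (0.0873) or 2 (0.0736), or hepatocyte JNKΔhepa replicate 3 (0.0727).

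Among the 14338 probe sets without exactly 1 gene symbol, which no comparison used, 33 differed between the genotypes in liver and 40 in hepatocytes, 17 of them in both.

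The lower endothelial and macrophage markers in JNKΔhepa hepatocytes may reflect fewer non-parenchymal cells in those preparations. Genes outside all lists that were depleted by isolation in the WT arrays (139 genes) had a median hepatocyte change of −0.165, with 114 of 139 below 0, lower than all 10000 level-matched random lists (−0.0914 to 0.0518), while 2170 genes little changed by isolation had a median of 0.035. Random lists do not keep the shared movement of depleted genes, so this rank can overstate the evidence. From array means, the change of the 139 genes was −0.236 in hepatocytes (95% interval −0.429 to −0.0423) and −0.143 in liver. The depleted genes were first chosen over both genotypes (169 genes, median −0.293) and then over WT arrays alone. In liver they also lay below all random lists under both choices (−0.0517 and −0.138). The comparison with random lists therefore does not by itself separate fewer such cells in the preparations from lower expression of such genes. Choosing on WT arrays favours genes that read low by chance in WT hepatocytes and high in WT liver. That pushes the hepatocyte change up and the liver change down, by an amount that was not tested. Lower expression within those cells throughout the mouse could also produce the lower markers. In whole liver the same 40 markers had a mean change of −0.00924 (95% interval −0.387 to 0.369), against −0.515 (−0.893 to −0.137) in hepatocytes. The liver interval leaves out −0.515 but overlaps the hepatocyte interval, and overlap does not test the difference. In liver the mean change was 0.0745 for endothelial markers (95% interval −0.241 to 0.39) and −0.102 for Kupffer cell markers (−0.571 to 0.367). The endothelial interval leaves out the −0.48 of hepatocytes but overlaps the hepatocyte interval (−0.795 to −0.165). The Kupffer cell interval leaves in most of a drop like that of hepatocytes (−0.553), so lower expression within those cells stays open. On single hepatocyte arrays the genotypes overlapped. The mean Kupffer cell marker level was 5.186 in WT replicate 2, below 5.257 in JNKΔhepa replicate 1. For endothelial markers these arrays read 6.39 and 6.409. WT replicate 3 read 5.725 for Kupffer cell and 6.696 for endothelial markers, so preparations of the same genotype differed too. Stellate marker means did not overlap (lowest WT 4.084, highest JNKΔhepa 4.048). A biological loss of these cells, or a different yield of the isolation, was not tested.

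Calls near Mapk9 may come from donor-strain DNA that flanks the Jnk2 null allele, since 16 of 392 genes within 20 Mb of it were called in liver or hepatocytes (Fisher's exact p = 0.00023). Outside that region, 20 of 43 shared calls had another within 5 Mb, where 10000 random gene sets gave a median of 9 and an upper 95% bound of 16 (permutation p = 0.004). Further donor segments that differ between the genotypes could give this. The random sets were not matched for expression level, and the clustered calls also held Rsad2 of the interferon list with Cmpk2 on chromosome 12. Gdpd3 lay within 5 Mb of Sec23ip on chromosome 7. Xaf1 of the interferon list, on chromosome 11, lay within 5 Mb of Myh10. Myh10 is inside the Mapk9 region, so Xaf1 was not counted among the 20. Runs included Camk2d, Ank2, Tifa, Fam241a and Rpl34 on chromosome 3, Pebp1, Acad10 and Kdm2b on chromosome 5, and Sorl1, Mcam, Apoa4, Nxpe2, Nnmt and Il18 on chromosome 9. Of the clustered calls, 0 had a neighbour whose symbol starts with the same 3 letters. Probe sets with several symbols had been left out, and likeness of symbols does not measure probe sequence. Probes shared by neighbouring paralogs are therefore not excluded. Genes called in one tissue alone were less clearly clustered (155 of 221, random median 144, permutation p = 0.09). An effect of JNK loss on neighbouring genes stays open, because genotype and flanking DNA coincide in this design and no genotyping was used here.

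The liver calls could come partly from cells other than hepatocytes. Their median ratio of hepatocyte change to liver change was 0.529 (95% bootstrap interval 0.444 to 0.653), with 92 of 174 calls at the same sign and at least 50% of the size, so the written bound lies inside the interval and the test stays open. Of the non-hepatocyte marker lists, 1 (stellate cells) passed in liver at the preset correlation (camera adjusted p = 0.0198; adjusted p = 0.482 with an estimated correlation; fry 0.441), and it was lost without liver WT replicate 1 (0.0755) or JNKΔhepa replicate 3 (0.113).

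The 6 mice make 10 splits into 3 and 3, too few for a share under 0.05. As many calls came from 1 of the 10 splits, the real one, in each case: liver gave 174 genes against 0 at most in another split, hepatocytes 158 against 53, the interaction 2 against 0, and the overlap 54 against 0. The 53 came from the split that puts WT replicate 2 with JNKΔhepa replicates 2 and 3. The hepatocyte count was highest without WT replicate 2 or JNKΔhepa replicate 1. A pattern partly aligned with genotype may thus add to the hepatocyte calls, and its share was not tested. For hepatocytes against liver, 1 of 100 splits drawn within genotypes, the real one, gave 17371 genes and the highest other gave 9316. These were deposited values, on which the overall levels of the tissues lie apart. The real split was therefore bound to give the most genes, and this test cannot exclude chance.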

How the results depend on the processing

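The settings without genes near Mapk9, the overlap at the stricter p, with 6 arrays or with a block, and the list tests under other scalings, without single arrays, without Mapk8 and Mapk9 or with a block were chosen only after the results were seen. Outside the settings named here, each count stayed within 1.5 times its value, and Mapk9, Adh6-ps1, Gdpd3, Pttg1, Rpl34, Cox6b2, Apoa4, Sorl1, Naip2 and Dusp8 passed in both tissues without any single array. Array background was not measured, so how far dim signal limits the calls is unknown.

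Counts are for the genotype effect in liver, the genotype effect in hepatocytes, the genotype by tissue interaction, hepatocytes against liver, and the overlap. At an adjusted p under 0.01 they were 55 in liver, 52 in hepatocytes, 1 for the interaction and 28 for the overlap, by the threshold's construction. Array weights gave 408 in liver and 4 for the interaction, the arrays of a tissue alone gave 77 in hepatocytes and an overlap of 31, and all probe sets gave 1 for the interaction and 30384 between the tissues, where more features were tested. Between the tissues, 8481 passed after quantile normalisation and 9448 at 1.5-fold. With the replicate number as a block, which pairs different mice across genotypes, the counts were 29 in liver, 80 in hepatocytes and 9 for the overlap. Those same-numbered arrays correlated at −0.12 to 0.112 in their residuals. With the mouse as a block, which pairs liver with hepatocytes, the counts were 2 for the interaction and 17423 between the tissues, and the list NRF2 targets and glutathione, hepatocytes against liver (0.0581) and the list Cell cycle, hepatocytes against liver (0.0676) no longer passed as deposited, while no other list call of these comparisons changed. Without each array the counts ran from 80 to 208 in liver, 61 to 387 in hepatocytes, 1 to 7 for the interaction, 17152 to 17329 between the tissues and 36 to 75 for the overlap. The cause was not tested except where the construction is named.

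In 37 list results the direction turned. Between the tissues, fry tests against 0 rather than against other genes, so the lower deposited level of hepatocytes turns the direction: adjusted p was 6.23e-09 for JNK cascade, bile acid and cholangiocyte lists, 0.00852 AP-1, 0.0174 PPAR-alpha, 0.0863 fatty acid synthesis, 0.029 sterol, 1.05e-05 xenobiotic, 6.59e-07 NRF2, 0.0011 unfolded protein, 1.12e-06 heat shock, 3.6e-08 p53, 0.000524 cell cycle, 5.74e-07 cytokines, 0.000314 acute phase, 2.96e-06 interferon, 0.00022 glucose, 0.000134 clock, 0.836 male-biased, 8.48e-05 female-biased, 0.000254 periportal and 2.92e-06 hepatocyte identity. Quantile normalisation turned bile acid (0.574), xenobiotic (0.176), NRF2 (0.834), cytokines (0.0484), acute phase (0.188) and hepatocyte identity (0.951). Centring turned cell cycle (0.517), the list Cytokines, chemokines and NF-kB targets, hepatocytes against liver (0.000344), interferon (0.0257), clock (0.194), female-biased (0.041) and cholangiocyte (0.0451) lists. Without hepatocyte WT replicate 2 the direction turned for the list Cell cycle, genotype effect in hepatocytes (0.746, lowest without another array 2.75e-06), the list Cell cycle, genotype by tissue interaction (0.00448, others up to 0.976) and the list Cell cycle, hepatocytes against liver (0.898, others down to 0.00743). The cause of these last turns was not tested. fry called heat shock and bile acid lists in liver, dedifferentiation and stellate lists in hepatocytes, and 31 between the tissues. It also called the JNK cascade in both tissues, which rests on the targeted Mapk8 and Mapk9: without them its adjusted p was 0.881 in liver and 0.383 in hepatocytes.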

Other observations

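The clock hypothesis below was tested as written beforehand, and the other values here were picked after they were seen.

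After quantile normalisation, further gene groups differed between hepatocytes and liver. Lymphocyte markers (median log2 difference −0.47, 13 lower and 1 higher of 18, limma's camera adjusted p = 7.56e-06; adjusted p = 0.0939 with an estimated correlation) and neutrophil and monocyte markers (median −0.366, 8 of 14 lower, adjusted p = 0.000648; adjusted p = 0.0939 with an estimated correlation) were lower in hepatocytes. Fatty acid synthesis (median 0.304, 10 higher and 1 lower of 19, adjusted p = 0.0083; adjusted p = 0.492 with an estimated correlation) and sterol synthesis genes (median 0.24, 7 of 20 higher, adjusted p = 0.016; adjusted p = 0.635 with an estimated correlation) were higher on this scale. Unfolded protein response genes were higher on it as well (median 0.247, 11 higher and 1 lower of 26, adjusted p = 0.0083; adjusted p = 0.364 with an estimated correlation). Dedifferentiation and cytoskeleton genes, which include those of other liver cells, were lower (median −0.344, 15 lower and 3 higher of 26, adjusted p = 0.000222; adjusted p = 0.25 with an estimated correlation). Extracellular matrix (median −0.648, 17 of 24 lower, adjusted p = 7.74e-10; adjusted p = 0.0732 with an estimated correlation), apoptosis (median −0.215, 13 lower and 2 higher of 26, adjusted p = 0.00912; adjusted p = 0.281 with an estimated correlation) and cytokine genes (median −0.267, 10 lower and 4 higher of 28, adjusted p = 0.0484; adjusted p = 0.596 with an estimated correlation) were lower, and male-biased genes (median 0.37, 8 of 17 higher, adjusted p = 0.0144; adjusted p = 0.596 with an estimated correlation), PPAR-alpha targets (median 0.198, 9 higher and 2 lower of 27, adjusted p = 0.0209; adjusted p = 0.635 with an estimated correlation) and glucose metabolism (median 0.139, 8 higher and 1 lower of 21, adjusted p = 0.0481; adjusted p = 0.389 with an estimated correlation) were higher after quantile normalisation. As deposited, where most genes read lower in hepatocytes, the balance of these 6 lists was different: 2 higher and 5 lower in fatty acid synthesis (median −0.0948), 0 and 12 in sterol synthesis (−0.303), 1 and 13 in the unfolded protein response (−0.205), 1 and 2 in male-biased genes (0.0162), 2 and 12 in PPAR-alpha targets (−0.295) and 4 and 13 in glucose metabolism (−0.319). After centring their medians were 0.76, 0.552, 0.65, 0.871, 0.56 and 0.535, so the balance of calls in these lists depends on the scaling, as does the sign of the median in all but the male-biased genes.

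A probe set of Hspa8, a constitutive heat shock protein gene, read −1.91 in liver and −1.71 in hepatocytes (SE 0.125 each) where the probe set used for the gene read −0.38 and −0.24. Hsd3b5, a male-biased steroid dehydrogenase gene, differed widely among the JNKΔhepa livers, at 8.33, 4.65 and 8.50 on the log2 scale, while the WT livers read 10.3, 10.9 and 9.74.

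The lower clock list in JNKΔhepa liver could reflect a different time of day of collection. Of 18 clock genes 0 passed limma in liver or hepatocytes at an adjusted p under 0.05, which met the bound set beforehand against this, but that bound was too weak, since standard errors of 0.0895 to 0.672 would hide changes of a size that matters. Per2 had a log2 change of −1.25 in liver (adjusted p = 0.102). The explanation stays open.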
